A study of Mus musculus with 47 samples.

How the data were processed

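Expression was measured in C57BL/6J mice on custom 1-colour arrays, with oligo-dT primed amplified cRNA and with random primed, directly labelled cDNA of each tissue, per the labels' protocols. Priming, amplification and labelling therefore differ together, and the contrast is between 2 whole labelling methods. In some tissues the wording of the extraction protocol also differs between the 2 arrays, per the labels. The title of the oligo-dT kidney sample names no priming, which was taken from its label protocol. SL10 has 1 oligo-dT array. The 13.5 dpc placenta has expression values only in the authors' value table, so 11 tissues and SL10 enter the expression fits. Methylated DNA was immunoprecipitated with an antibody to 5-methylcytidine and labelled with Cy5, against Cy3 input, per the labels. Whether the arrays of a tissue come from separate animals is not stated per the labels.

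Expression intensity was deposited as the processed Cy3 signal of Agilent Feature Extraction 9.1.3.1, background-subtracted and detrended within the array without normalization between arrays, per the file headers. Methylation intensity of both channels comes from Feature Extraction 9.5.3.1, background-subtracted with linear dye normalization, per the file headers. The log10 ratio column is Cy5 over Cy3, per the file headers. The authors' methylation value table is the same ratio in log2 units, not re-centred, with column medians from -0.4 to -0.16, and 175,983 of its 176,485 lines equal such a ratio within 0.011 log2. The authors' expression value table holds intensity on a linear scale, which is the processed signal times 1 constant per array (1 to 7.39) floored at 5; the rule behind the constants is unstated. Its column medians ran from 5 (small intestine and lung, at the floor) to 58.4 with oligo-dT and from 107.2 to 252.3 with random primers, and that of SL10 was 18.97. Of 5,346 lines above the floor on every array 5,244 equalled a probe times the constant within 0.01 log2.

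Control spots and spots with an outlier mark were left out, and spots of 1 probe averaged. In the methylation fits 476 probes (9 tissues) and 565 (all tissues) with such a spot were dropped. Expression values were log2 signal minus the 75th percentile of each array, and methylation values log2 of Cy5 over Cy3 minus the array median. The 2 arrays of male kidney DNA were averaged into 1 sample. Probe coordinates are emptied in the files and the header names build mm7, so probes were grouped into 3,664 loci by shared accessions (median 25 probes, 2 to 107): 19 on X, 1,128 autosomal, none on Y, and 2,517 without a chromosome. Gene names came from the files and the given tables. They covered 3,087 forward expression probes (2,944 genes) and 1,082 loci with 1 name, and 12,923 expression probes had none. Of 2,960 probes for the reverse strand 2,425 belonged to 668 named genes. The array holds 6,348 pairs of sense and antisense transcripts.

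Fits used limma 3.58.1 in R 4.3.3 with the data.table package (1.17.8) and statmod 1.5.0, and python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Priming was tested with tissue as a block on probes well above background on at least 1 in 2 arrays of either priming, and sex with tissue as a block, both with trended, robust variances. Tissues were tested with an F test and by contrasts of each tissue with the mean of the others (methylation: with the other adult somatic tissues), with priming or sex as a fixed effect, on probes well above background on at least 2 arrays for expression. A result passed at an adjusted p under 0.05 (Benjamini-Hochberg), with a log2 difference of at least 1 for single tissues in expression and 0.5 in methylation. SL10 and testis methylation rest on 1 array each, assumed to vary like the others. Correlations over tissues were tested with 10,000 permutations of tissues or re-pairings of probes. Labels were exchanged within tissues 100 times for priming and for sex.

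Gene lists with at least 5 measured members were tested with limma camera at a correlation of 0.01 and again with an estimated correlation: 8 lists for priming, 99 tests over tissues in expression, 3 for sex and 33 over tissues in methylation. Wildcards were taken literally, so that the germline list holds Adamts genes, the placenta list Prlr and the Hox list Hoxb5os. The mitochondrial, stomach and adipocyte lists had no member on the arrays. For priming the kidney, exocrine pancreas and decidua lists had no tested member, and for methylation the red blood cell and histone lists. Genes were named by a rule: the 10 largest rises and falls of a comparison with the same sign in all but 1 tissue (the 3 largest per tissue), up to 4 members of each list, and 12 fixed imprinted or antisense genes where measured. A gene with several probes was represented by the probe with the highest mean level, and a gene with several loci by the one with most probes, since nearness to the start could not be used. Of genes the rule names, some are not printed for length. Where signals of 1 side stayed under background, a fold is given as "at least".

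The comparisons, thresholds, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were normexp (for expression with an offset of 50 and always together with quantile normalization), quantile normalization alone, the authors' tables, other filters, 1 value per gene, blocks for scan date, no tissue block, and each tissue or array left out. Other alternatives, chosen after seeing the data, are named in the closing section. The scripts were tested on simulated data, in which 66 or 67 probes or loci changed at each size. Expression was simulated with all 18,970 probes, so the changed share was far below that called between the real primings. Recovery by adjusted p depends on this share, so the rates below may differ from those of the real comparisons. Priming changes of log2 1 and 2 were recovered for 8.96% and 77.3% of probes, and single-tissue expression changes of 2 and 4 for 20.9% and 81.8%. With 1 tissue changed, the F test over tissues in expression recovered 0% at 2 and 12.1% at 4. Of its calls 1 (11.1%) was an unchanged probe. Sex differences in methylation of 0.5 and 1 were recovered for 52.2% and 98.5% of probes, and single-tissue methylation of 0.5 and 1 for 11.9% and 67.2%. Differences of 0.5 in loci were recovered in full for sex and single tissues. Recovery was counted by adjusted p and direction alone, without the size thresholds used for single tissues. The median estimate of single-tissue loci at 0.5 was 0.503, so many of them could fall short of the 0.5 threshold.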

Results

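Transcripts of 11 mouse tissues were read on 2 expression arrays each, 1 primed with oligo-dT and 1 with random primers, and a fibroblast line on 1 oligo-dT array. Methylated DNA was read on 22 arrays: 9 tissues of both sexes (male kidney on 2 arrays), testis, and placenta at 10.5 and 13.5 dpc. Between 36.4% (small intestine) and 61.4% (placenta) of the expression spots were well above background with oligo-dT, and between 62.1% (liver) and 82.8% (brain) with random primers. In the input channel of the methylation arrays at least 99.8% of spots were well above background. Errors are standard errors. Nothing in the records says that arrays came from separate animals, so p values measure only the spread between samples, which may be technical.

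Random priming raised long non-coding RNAs and lowered ribosomal protein messages. All 8 listed non-coding, nuclear or antisense RNAs rose (median log2 change 2.30, adjusted p = 0.0373; adjusted p = 0.135 with an estimated correlation), and all 7 ribosomal protein genes fell (median -3.08, adjusted p = 7.2e-04; 0.0191 with an estimated correlation), or 6 of 7 under quantile normalization with and without normexp. Snhg14, the long host transcript of small nucleolar RNAs in the Prader-Willi region, rose by 3.33 ± 0.31 in 11 of 11 tissues, Meg3 by 2.60 ± 0.40 in 11 of 11, Rmst by 2.31 ± 0.40 in 10 of 11 and Kcnq1ot1, the antisense transcript of the Kcnq1 imprinting centre, by 2.29 ± 0.28 in 11 of 11. Of the 11 oligo-dT arrays all were well above background for Snhg14, but 3 for Meg3, 5 for Rmst and 2 for Kcnq1ot1, so these differences were measured largely against background. Meg3 (1.77, adjusted p = 0.0584) and Rmst (1.11, 0.172) did not pass within scan date 2. Rps4l fell by 5.94 ± 0.22, Rps25 by 3.63 ± 0.33 and Rps29 by 3.97 ± 0.26, each in 11 of 11 tissues (Rps29 was saturated on 7 of the 11 oligo-dT arrays, so its value is a lower limit of the fall), and Rps27a fell by 3.08 ± 0.42 in 10 of 11. Both histone genes on the array, whose messages carry no poly(A) tail, rose: H3c14 by 2.80 ± 0.33 in 11 tissues and H4c2 by 1.19 ± 0.31 in 9. H4c2 did not pass in tissues whose 2 arrays had different extraction wording (0.56, adjusted p = 0.314) or within scan date 3 (0.15, 0.814). The median of all probes moved by 0.47 between primings, and by 0.07, 0.29 and 1.80 under 3 other scalings. Against that shift the non-coding list stood at 1.83 (1.42, 2.11 and 1.83 under the others) and the ribosomal list at -3.56 (-1.44, -2.27 and -3.56).

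The X-inactivation transcript Xist rose by 1.49 ± 0.22 in 11 of 11 tissues on the probe with the highest level, and its 15 other probes rose by 0.28 to 6.96. Its antisense partner Tsix rose by 2.90 ± 0.43 in 11 of 11 on 1 probe, while 4 other probes gave 0.21, 0.52, 0.56 and -1.98 and the mean of its probes 0.44 (adjusted p = 0.203). Among 46 imprinted genes 19 rose and 18 fell (median 0.01, mean -0.34, adjusted p = 0.345), and the median was -0.14 under quantile normalization (16 rose and 17 fell) and 1.34 with the percentile over probes well above background on every array (28 and 14). The growth factor Igf2 rose by 4.32 ± 0.26 and its clearance receptor Igf2r fell by 4.29 ± 0.21 (-0.13, adjusted p = 0.661, with 1 value per gene and reverse-strand probes included), as did Nap1l4 (63.8-fold lower) and Osbpl5 (-4.97 ± 0.40), each in 11 of 11 tissues. Gnasas1, antisense to Gnas, rose by 1.68 ± 0.34 in 10 of 11 but did not pass in tissues with different extraction wording (1.07, adjusted p = 0.120) or within scan date 3 (0.55, 0.566). Gnas itself did not pass (0.10 ± 0.32, adjusted p = 0.793, higher in 5 of 11). Gnas passed upward with the percentile over probes well above background on every array (1.42, adjusted p = 0.000299) and within scan date 1 (0.93, 0.0492), and downward with 1 value per gene and reverse-strand probes included (-1.06, 0.00421). Peg3 rose by 0.87 ± 0.32 in 8 of 11 (a second probe gave 1.25), a call lost without brain (0.76, adjusted p = 0.0572), kidney (0.76, 0.0583) or testis (0.75, 0.0540). It was also lost under quantile normalization (0.74, 0.0607), in tissues with different extraction wording (0.30, 0.640) and within scan date 1 (0.85, 0.123). Within scan date 3 the direction of Peg3 turned, and with no tissue block Peg3 was not called. Snrpn fell by 1.26 ± 0.42 in 8 of 11, which did not pass under quantile normalization with (-0.04) or without normexp (-0.31) and turned to 0.07 with that percentile. Nor did Snrpn pass in tissues with the same extraction wording (-0.48, adjusted p = 0.332), within scan date 1 (-0.0039, 0.993) or without small intestine and lung (-0.64, 0.0655).

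**Figure D1:**
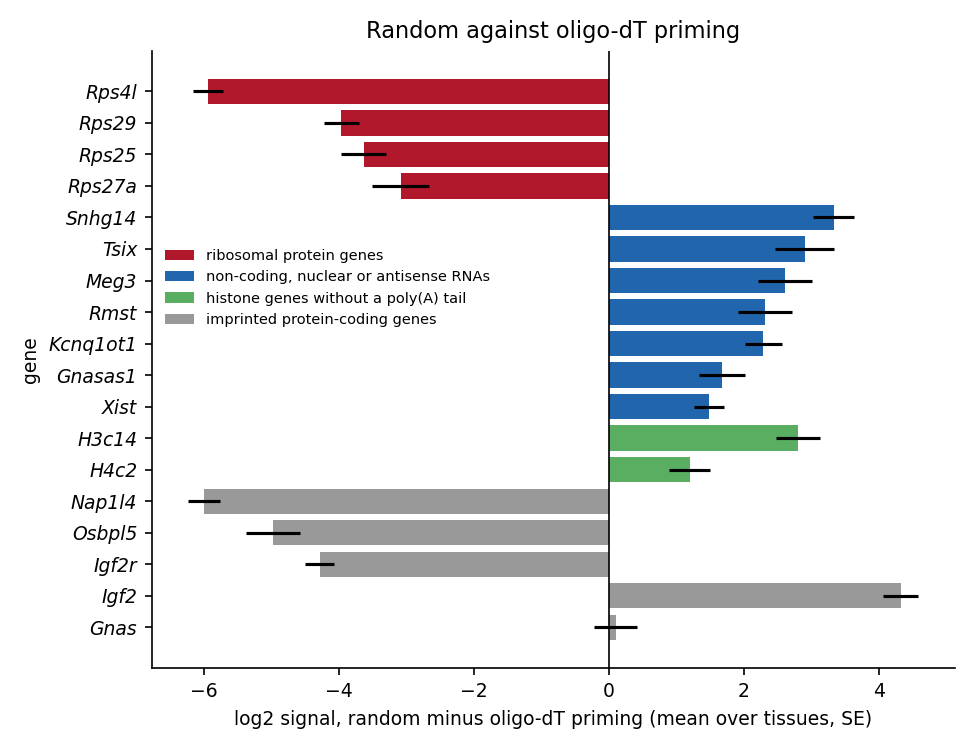
Log2 difference between random and oligo-dT priming for members of 4 gene groups, as means over 11 tissues with standard errors. Rps29 was saturated on 7 oligo-dT arrays. The zero line depends on the scaling, which moved the median of all probes by 0.07 to 1.80.

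Over all forward and reverse probes 11,111 of 15,032 passed between the primings, 6,479 higher with random primers and 4,632 lower. The 10 named genes with the largest rise were B020011L13Rik (at least 213-fold), Grap2 (8.48 ± 0.38), A730081D07Rik (7.87 ± 0.31), 4930573H18Rik (7.34 ± 0.44), Pip5k1bos (at least 58.6-fold), 1700085C21Rik (6.89 ± 0.34), BC030500 (6.85 ± 0.41), Tmem258 (6.76 ± 0.27), Shc3 (6.58 ± 0.38) and Chd5 (6.43 ± 0.39). With oligo-dT Tmem258 was well above background on 6 of 11 arrays, A730081D07Rik, 1700085C21Rik and Chd5 on 3, Grap2 and Shc3 on 2, 4930573H18Rik and BC030500 on 1 and the other 2 on 0, so the sizes of these rises rest on levels near background. The largest falls were those of the opioid growth factor receptor Ogfr (-8.89 ± 0.24), the endoplasmic reticulum protein Erp29 (-8.66 ± 0.28), Nme2 (-8.56 ± 0.27), Ccdc117 (-8.30 ± 0.34, other probe 0.84), Tsn (-7.70 ± 0.26), Zfp672 (-7.43 ± 0.26), Arsa (-7.34 ± 0.23), the mismatch repair gene Mlh1 (-7.08 ± 0.27; -0.15, adjusted p = 0.594, with 1 value per gene and reverse-strand probes included), the adiponectin receptor Adipor2 (-7.03 ± 0.24) and Laptm4a (-6.95 ± 0.28). Each of these 20 genes changed the same way in 11 of 11 tissues. The split between higher and lower depended on the scaling and the probes: 9,859 and 2,866 with the percentile over probes well above background on every array, but 996 and 2,724 when only those probes were tested. It was 6,457 and 7,135 with no filter and 808 and 1,031 with 1 value per gene. The authors' value table, which has other scaling, a floor at 5 and the 13.5 dpc placenta, gave 9,116 and 1,897.

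Probes for the reverse strand, of named genes or not, rose more than others, with 1,073 of 1,870 higher and 228 lower. The strand was taken from the probe names. Of 2,809 compared pairs of a forward and a reverse probe, 334 overlapped on opposite strands by at least 15 bases and 0 on the same strand. Their median stood 0.72 above that of all probes (0.16, 0.62 and 0.72 under the other scalings), against -0.15 for sense transcripts of a pair (2,605 higher and 2,133 lower of 6,405), -0.09 for antisense transcripts (2,660 and 2,082 of 6,329) and -0.84 for genes outside the pairs (141 and 189 of 428). With oligo-dT 28.3% of reverse-strand probes were well above background, and with random primers 59.8%.

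Other gene lists moved both ways with priming. Of 6 endothelial and macrophage markers 4 fell and 1 rose (adjusted p = 0.102): Cd14 (-4.46 ± 0.28) and Kdr (-3.57 ± 0.27) in 11 of 11 tissues, Csf1r (-3.15 ± 0.47) and Adgre1 (-2.37 ± 0.34) in 10 of 11. Csf1r did not pass within scan date 2 (-1.64, adjusted p = 0.0967), nor Adgre1 within scan date 3 (-0.84, 0.257). Of 8 Hox genes 4 rose and 3 fell, among them Hoxa3 (2.43 ± 0.40) and Hoxb2 (-2.94 ± 0.23), against 2 and 3 under normexp with quantile normalization and 5 and 2 with the percentile over probes well above background on every array. Hoxa3 did not pass within scan date 3 (0.36, adjusted p = 0.477). Their median was 0.78, the mean -0.03 and the test pointed down (adjusted p = 0.783). Of 16 other developmental transcription factors 8 rose and 3 fell (Foxf1 4.66 ± 0.32, Nkx6-2 -4.30 ± 0.67 but -2.79 and adjusted p = 0.0543 within scan date 1; set adjusted p = 0.490), of 12 germline genes 3 and 5 (median -0.48, adjusted p = 0.345), and of 7 spermatogenic markers 4 and 2 (adjusted p = 0.783). With that percentile 11 of the developmental factors rose and 1 fell, 6 and 2 of the germline genes (median 0.85) and 5 and 0 of the spermatogenic markers, while quantile normalization gave 1 and 7 germline genes. Among lists too short to test, 3 of 4 placenta markers, 2 of 3 genes that escape X inactivation (Xist and Mid1, at least 7.35-fold), 1 of 2 brain markers (Syn1, 4.07 ± 0.25), 1 of 2 B cell markers (Pax5, 1.54 ± 0.37), 1 of 2 skeletal muscle markers and the small intestine marker Cdx2 (1.41 ± 0.60) rose. The Cdx2 call was lost under quantile normalization with (0.0084) and without normexp (1.09). In the same lists 1 placenta marker (Prlr, -2.86 ± 0.22), 1 gene that escapes X inactivation, 1 skeletal muscle marker, 1 of 2 cell cycle genes (Pcna, -2.91 ± 0.25) and the lung marker Foxj1 (-5.14 ± 0.47; -0.67, adjusted p = 0.104, with 1 value per gene and reverse-strand probes included) fell. The heart muscle (2), fibroblast (2), T cell (1), liver (1) and red blood cell (1) markers did not pass, but 1 fibroblast marker rose under quantile normalization with and without normexp. With the percentile over probes well above background on every array both fibroblast markers and 1 marker in each of the other 4 lists rose. Every list gave the same counts when adjusted over the list alone.

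Testis had the most probes higher than in the other tissues. There the antizyme Oaz3 rose by 12.74 ± 0.52 log2 over the other tissues, the diazepam-binding-like gene Dbil5 by 10.93 ± 0.49 and 1700074P13Rik by at least 1234-fold. Of 8 spermatogenic markers 7 rose there (8 when adjusted over the list alone, median 6.98, adjusted p = 4.8e-09; 0.0179 with an estimated correlation), among them Spata4 (8.28), Tekt2 (8.05), Hspa1l (7.81) and Spata32 (7.38). The meiotic gene Syce1 (9.17), Stk31 (5.95) and Dpep3 (5.54) were among 6 of 13 germline genes that rose there. In brain the myelin gene Mbp rose by 9.52 ± 0.61, the synuclein Sncb by 8.43 ± 0.73 and the GABA transporter Slc6a1 by 8.26 ± 0.53. Heart carried myoglobin (Mb, 10.28 ± 0.80), the mitochondrial creatine kinase Ckmt2 (9.78 ± 1.14, other probe 5.64) and Trdn (7.53 ± 0.88). Kidney carried the salt transporter Slc12a1 (10.86 ± 0.67), the cation transporter Slc22a2 (9.22 ± 0.79) and Gpx3 (8.13 ± 0.50), and liver Dpys (10.54 ± 0.72), the elastase Cela2a (9.71 ± 0.70) and Serpina3m (9.33 ± 0.90). Thymus carried the recombinase gene Rag1 (12.04 ± 0.59), Satb1 (7.36 ± 0.41) and the T cell kinase Lck (6.36 ± 0.84), and spleen Cela2a (10.11 ± 0.70), the B cell kinase Blk (6.80 ± 0.74) and Cd2 (6.00 ± 0.67). Cela2a was the 1 measured marker of exocrine pancreas. All changes are on the log2 scale, from 2 arrays of the tissue against 20 of the others, with both arrays in the same direction. Mb and Ckmt2 were saturated on 1 heart array, Dbil5 on 1 testis array and Rag1 on 1 thymus array.

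Placenta, small intestine and lung shared a scan date and array format, apart from the other 8 tissues, so their differences from these cannot be told apart from that batch. Placenta at 10.5 dpc carried granzyme Gzmc (10.07 ± 0.82), Serpinb9b (9.86 ± 0.57) and Hoxa11 (8.86 ± 0.42), the 1 measured marker of decidua, yolk sac and embryo. Small intestine carried 9130208D14Rik (9.91 ± 0.66), the gut homeobox gene Cdx1 (8.91 ± 1.01) and Prss32 (8.78 ± 1.32). Stomach carried Psca (9.47 ± 1.18), saturated on 1 array, the keratin Krt19 (6.43 ± 0.53) and Hrnr (6.41 ± 1.16), and lung carried Cyp2f2 (6.16 ± 0.93), Clic3 (5.49 ± 0.46) and Mb (5.14 ± 0.80). Without the oligo-dT array of the tissue the calls of Prss32 (5.05, adjusted p = 0.101), Hrnr (3.62, 0.861), Cyp2f2 (6.01, 0.0728) and Mb in lung (2.98, 0.153) were lost. Of 53 imprinted genes 19 rose and 2 fell in placenta (22 and 3 over the list alone, median 1.03, adjusted p = 4.8e-09; 0.0588 with an estimated correlation), with Phlda2 (8.03 ± 0.63), Dio3 (7.38 ± 0.94), the cell cycle inhibitor Cdkn1c (5.59 ± 0.55) and Slc38a4 (5.12) in front. The same list fell in thymus (10 fell and 1 rose, 12 and 1 over the list alone; adjusted p = 8.8e-05; 0.111 with an estimated correlation) and spleen (5 fell, 6 over the list alone; 1.6e-06; 0.0727). In brain 13 rose and 7 fell without the set passing (adjusted p = 0.0773): Meg3 (7.86 ± 0.70), Rasgrf1 (5.87, other probe 6.08) and Snurf (5.75) rose, and Phlda2 was at least 12.6-fold lower.

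**Figure D2:**
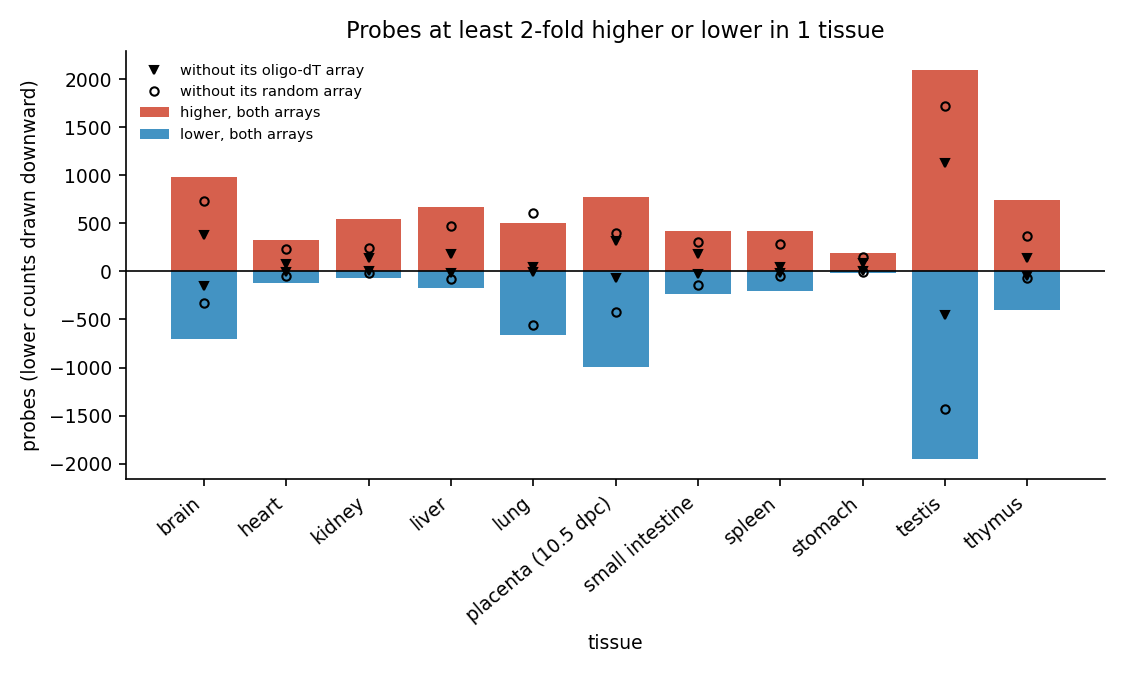
Probes at least 2-fold higher or lower in 1 tissue than in the mean of the other 10, with both arrays and without each of the tissue's own arrays.

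Hox genes rose in kidney, a mesoderm-derived organ, with 4 of 10 past (6 over the list alone, median 2.68, adjusted p = 3.6e-07; 0.0136 with an estimated correlation): Hoxb2 by 3.73 ± 0.42, Hoxa11 by 3.04 ± 0.42, Hoxb5os by 4.69 and Hoxb9 by 4.05. Without the oligo-dT kidney array Hoxa11 (2.41, adjusted p = 0.0851), Hoxb5os (2.55, 0.733) and Hoxb9 (2.26, adjusted p = 1) were not called, Hoxb9 was also lost without each of many other single arrays and with that percentile (3.79, 0.0747), and under normexp with quantile normalization Hoxa11 stood at 0.66. The other list results below, adjusted p values first with a fixed correlation of 0.01, did not pass with an estimated one. Endothelial and macrophage markers (6) rose in heart (2 genes, 3 over the list alone, adjusted p = 0.0135 and 0.131 with an estimated correlation), lung (2, 4 alone, 0.00507 and 0.111), placenta (1, 4 alone, 0.0341 and 0.173) and spleen (1, 2 alone, 0.00812 and 0.126) and fell in brain (3, 4 alone, 0.00984 and 0.127) and testis (4, 4 alone, 0.00575 and 0.112), with Pecam1 at -4.36 ± 0.55 in testis. Germline genes (13) rose in testis (6 higher and 1 lower, the same alone, 0.00575 and 0.0744) and placenta (5, 5 alone, 0.00445 and 0.0727), including Pramel13 (6.90) and Adamts2 (4.84) in placenta, and fell in small intestine (1, 3 alone, 0.0265 and 0.127) and in liver, where no gene passed (limma, also not over the list alone, 0.0244 and 0.127). Other developmental transcription factors (21) rose in brain (6, 7 alone, 0.0093 and 0.0727), with Pax6 at 4.51 ± 0.64, and fell in lung (5 lower and 1 higher, 6 and 1 alone, 0.0135 and 0.0727). In lung 0 of them were lower under normexp with quantile normalization and 2 without normexp. Placenta markers (5) rose in placenta (2, 3 alone, 0.00445 and 0.0727), with Ascl2 at 5.11 ± 0.52. The same list rose in small intestine (2, Ascl2 and Prlr, 3 alone, 0.0104 and 0.0744) and fell in spleen (1, Prlr, 3 alone, 0.00575 and 0.0727). Prlr is in that list only through a wildcard. Ribosomal protein genes (7) fell in brain (3, 5 alone, 0.00327 and 0.0700) and rose in placenta (2, 4 alone, 0.00121 and 0.0588), with Rps4l at 2.67 ± 0.41. Non-coding RNAs (9) rose in brain (2, 3 alone, 0.0339 and 0.128) and placenta (1, 1 alone, 0.0179 and 0.112) and fell in kidney, where 1 gene passed over the list alone (0.0442 and 0.133), and Hox genes fell in thymus (2, 2 alone, 0.0135 and 0.0744). In thymus 0 Hox genes were lower under quantile normalization with or without normexp, and Hoxb2 was not called without the random (-1.77, adjusted p = 0.188) or the oligo-dT array (-1.66, 0.291). No listed endothelial gene passed in placenta under quantile normalization, no germline gene in small intestine under normexp with quantile normalization or with the percentile, and no non-coding RNA in placenta under normexp with quantile normalization.

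Several short marker lists, not tested as sets, rose in their own tissue. Both brain markers rose in brain (Mbp and Syn1, 2.68 ± 0.46), and all 3 T cell markers in thymus (Rag1, Lck and Cd2, 6.33 ± 0.67). So did both B cell markers in spleen (Blk and Pax5, 5.21), both small intestine markers (Cdx1 and Cdx2, 5.29), 1 of 2 heart muscle markers (Ryr2, 4.43; both over the list alone), the kidney marker Slc12a1, the liver marker Cyp2e1 (saturated on both liver arrays) and the lung marker Foxj1 (4.42, and 5.33 in testis). Calls lost without an array of the tissue were those of Syn1 (2.26 without random, adjusted p = 0.0545), Cdx2 (2.92 without oligo-dT, 0.368), Ryr2 (2.44 without random, 0.716; 6.41 without oligo-dT, 0.0523; also lost without single arrays of liver, spleen or stomach) and Foxj1 in lung (2.57 without oligo-dT, 0.290; 2.32 under normexp with quantile normalization, 0.216). Ryr2 did not pass within scan date 2 (3.48, 0.0888). Both cell cycle genes rose in thymus, Top2a by 5.13 ± 0.42 and Pcna by 2.52 ± 0.47 (2.25, adjusted p = 0.162, without oligo-dT). Both histone genes rose there too, H3c14 by 2.48 (1.64, 0.398, without random and 3.33, 0.0705, without oligo-dT; 2.11, 0.0630, under normexp with quantile normalization) and H4c2 by 2.28 (1.92, 0.301 and 2.63, 0.173), each saturated on 1 thymus array. Serpine1, 1 of 2 fibroblast markers, rose by 7.65 ± 0.55 in placenta and 3.17 ± 0.55 in heart. Of genes that escape X inactivation 2 of 3 fell in testis. Testis is male and the sex behind the other expression arrays is not given here, so tissue and sex cannot be told apart for these genes. Xist fell in testis by 1.27 on the brightest probe, a call lost without either testis array (-0.86, adjusted p = 0.386, and -1.67, 0.0945), without some single arrays of other tissues, with the percentile over probes well above background on every array (-0.95, 0.168) and within scan date 2 (-0.998, 0.140). It stood at -2.68 to -7.83 on the other 15. Snrpn rose in brain (3.97, but 3.94 and adjusted p = 0.0764 without oligo-dT), as did Peg3 in placenta (8.58-fold, and by log2 3.84 on the other probe). The Peg3 call was lost without either placenta array (2.96, adjusted p = 0.0534, and 3.24, 0.0586). Igf2r rose in placenta (1.93, but 1.38 and 0.123 without random) and fell in testis (-2.61). Skeletal muscle and red blood cell markers passed in no tissue.

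Over all 11 tissues 5,635 of 17,651 probes differed, and single-tissue contrasts gave 7,661 higher and 5,546 lower calls (5,903 and 2,636 under normexp with quantile normalization; 5,576 and 2,317 on the authors' value table, which adds the 13.5 dpc placenta). Testis had 2,092 probes higher and 1,955 lower, but 1,127 and 449 without its oligo-dT array. Brain had 982 and 703 (379 and 156 without oligo-dT, 736 and 331 without random), placenta 773 and 999 (313 and 70; 397 and 421) and stomach 186 and 21 (87 and 0; 145 and 9). The 2 primings ranked probes of a tissue with Spearman correlations between 0.11 (small intestine) and 0.60 (testis).

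Sense and antisense transcripts of a pair rose and fell together over tissues more often than re-paired transcripts. The median correlation of 5,666 pairs was 0.145, against 0.021 after re-pairing and 0.045 as the highest of 10,000 re-pairings (permutation p = 0.0001, the smallest they can give). Among 178 pairs with 2 named genes the closest were 1700016J18Rik and Armc2 (0.93), the mitotic spindle gene Nusap1 and the kinetochore gene Oip5 (0.91), Bcl2l14 and 4933406J09Rik (0.91) and Kcnmb4os2 and the potassium channel subunit Kcnmb4 (0.91), and the most opposed were Rab5a and Pp2d1 (-0.82), Lctl and Zwilch (-0.71) and 1700066B19Rik and Ecscr (-0.67). In all, 376 pairs (6.64%) lay above 0.734 and 99 (1.75%) below -0.652, the points that leave 2.5% of re-paired correlations on each side. On random arrays alone the median was 0.066.

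**Figure D3:**
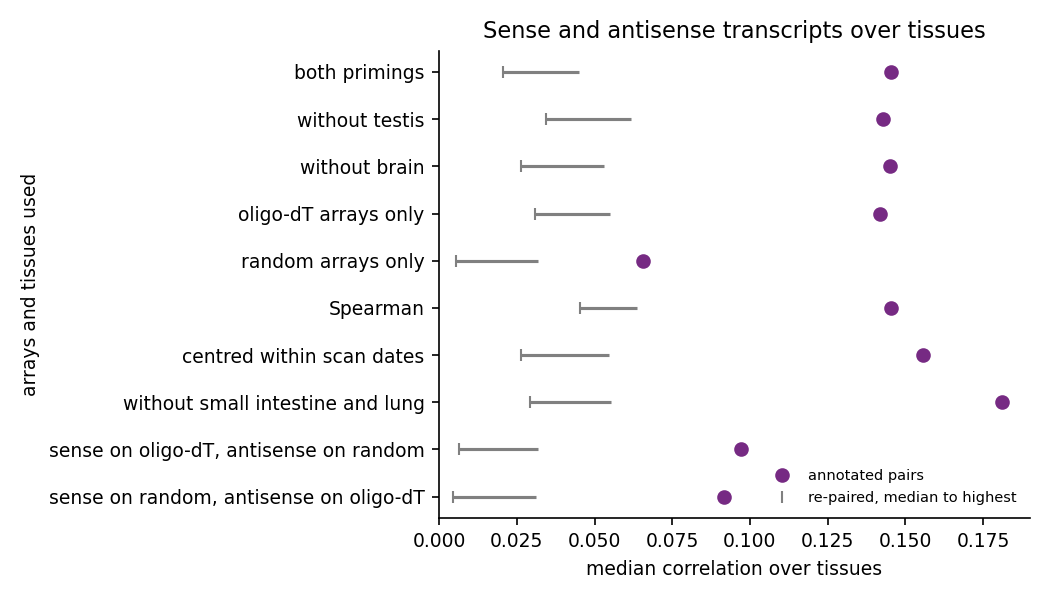
Median correlation of sense with antisense transcripts over tissues, by the arrays and tissues used, beside the median and the highest value after re-pairing.

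Females carried more methylation than males on the X chromosome. Of 19 X-linked loci 18 were more methylated in females (median log2 difference 0.87, limma), and they were higher as a set (p = 9.4e-109; 3.2e-05 with an estimated correlation). The protocadherin gene Pcdh19 was higher by 1.64 ± 0.05 (3.12-fold), the scaffold gene Cask by 1.54 ± 0.05 (2.90-fold), Pdzd11 by 1.34 ± 0.05, Rbm3os by 1.30 ± 0.05, the serotonin receptor gene Htr2c by 1.21 ± 0.06, Chst7 by 1.15 ± 0.06, Zfx by 1.12 ± 0.07, 2610002M06Rik by 1.12 ± 0.04, Pola1 by 1.08 ± 0.04 and A230072E10Rik by 0.87 ± 0.04, each in 9 of 9 tissues. Ndufb11 (0.82), Uxt (0.71), 9530027J09Rik (0.68), Syn1 (0.64), Pdzd4 (0.49), Dcaf12l2 (0.48), Tmem47 (0.44) and Lancl3 (0.33) followed, also in 9 of 9. The exception was 1700013H16Rik (0.09 ± 0.09, adjusted p = 0.816, higher in 6 of 9), which had a high mean in both sexes (2.92 and 2.83). It passed under quantile normalization (0.18, adjusted p = 0.00621). Within single tissues the median of the X-linked loci ran from 0.66 (liver) to 0.97 (kidney), with 18 or 19 of 19 higher.

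**Figure D4:**
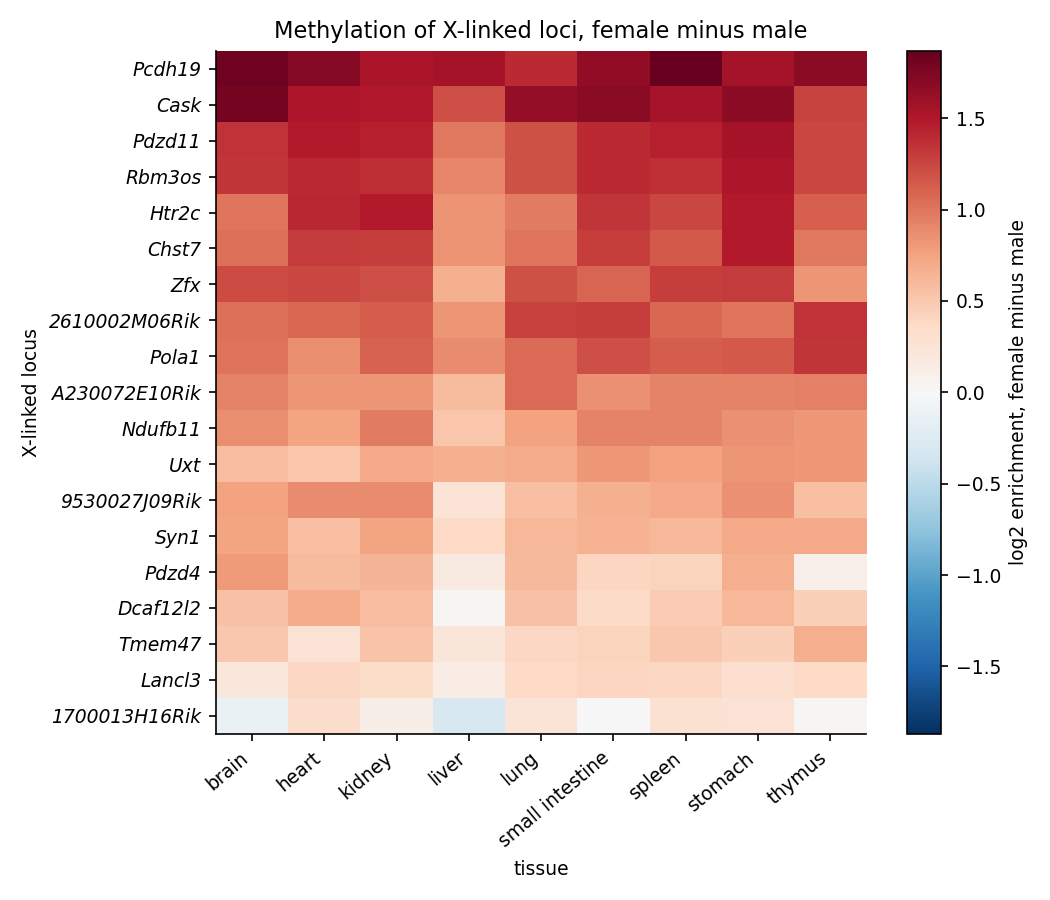
Female minus male log2 methylation enrichment of the 19 X-linked loci in 9 tissues, in order of the mean difference. Arrays of single tissues had 1 sample per sex.

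No autosomal locus was higher in females (limma, 0 of 1,128 at an adjusted p under 0.05, but 1 under normexp, with scan date as a block, without heart or without thymus, and 2 in tissues whose sexes were scanned on 1 date), and 5 were lower, among them Gm5796 (-0.24 ± 0.03), the class Ib histocompatibility gene H2-T23 (-0.16 ± 0.04) and Cfap299 (-0.11 ± 0.02), each lower in 9 of 9 tissues. H2-T23 was not called without brain (-0.16, adjusted p = 0.0649), lung (-0.15, 0.0931) or stomach (-0.16, 0.0557) or when scaled by the median absolute deviation (-0.16, 0.114). Nor was Cfap299 without brain (-0.09, 0.0706), liver (-0.11, 0.0547) or lung (-0.09, 0.0605) or under quantile normalization (-0.09, 0.0761). Neither was called with scan date as a block (H2-T23 -0.08, adjusted p = 0.292; Cfap299 -0.08, 0.157) or in tissues whose sexes were scanned on 1 date (-0.09, 0.137; -0.07, 0.114). Among 2,517 loci without a chromosome 27 were higher and 5 lower. In total 55 of 3,664 loci passed (45 higher and 10 lower). The lower ones depended on the setting, with 46 higher and 64 lower under normexp, 49 and 42 in tissues whose sexes were scanned on 1 date, and 47 and 75 without thymus. Of 98,200 probes 991 passed, 864 higher and 127 lower (1,145 and 364 without thymus), of which 326 and 2 lay in X-linked and 38 and 40 in autosomal loci. Imprinted genes did not pass as a set (12 loci, adjusted p = 0.485, 1 at an unadjusted p under 0.05), with Gnas at -0.11 ± 0.07 (adjusted p = 0.728, lower in 7 of 9), nor did developmental transcription factors (10 loci, median 0.00, adjusted p = 0.485, 0 unadjusted) or germline genes (5 loci, adjusted p = 0.981, 0 unadjusted). Of the short lists only Syn1 among the brain markers passed. Of 4 Hox and 4 ribosomal loci 1 each had an unadjusted p under 0.05, and the B cell, cell cycle, decidua, heart muscle, skeletal muscle and spermatogenic loci had none.

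Methylation at Pax8, Hoxa3 and Ebf1 differed between tissues. Pax8, a thyroid and kidney regulator, was more methylated in small intestine (1.84 ± 0.07) and stomach (0.65 ± 0.07) and less in spleen (-0.87 ± 0.07), thymus (-0.93 ± 0.07) and liver (-0.53 ± 0.07, but -0.39 under normexp and -0.49 under quantile normalization, short of the 0.5 threshold). Hoxa3 was more methylated in thymus (1.25 ± 0.08) and spleen (1.19 ± 0.08) and less in brain (-1.34 ± 0.08) and heart (-0.59 ± 0.08). Gbx2 was higher in spleen (0.92 ± 0.05) and thymus (0.89 ± 0.05). Ebf1, a B cell and neural factor, was higher in brain (1.31 ± 0.12), stomach (0.73 ± 0.12) and kidney (0.62 ± 0.12) and lower in spleen (-0.85 ± 0.12), thymus (-0.74 ± 0.12), liver (-0.67 ± 0.12) and small intestine (-0.55 ± 0.12). Under normexp Ebf1 in stomach (0.43), kidney (0.36), spleen (-0.27), liver (-0.41) and small intestine (-0.43) and Gbx2 in spleen (0.497) stood short of the 0.5 threshold. Ebf1 was also not called with scan date as a random block in kidney (0.53, adjusted p = 0.05001) and small intestine (-0.56, 0.103), nor without the male (0.70, 0.0620) or female sample of kidney (0.54, 0.164) or the male sample of small intestine (-0.46, 0.170). Brain also led in Tor4a (1.37 ± 0.04), Prdm8 (1.28 ± 0.07), Lhx3 (1.25 ± 0.08) and the imprinted Grb10 (0.63 ± 0.05, but 0.36 and not called under normexp). Kidney led in Hoxc5 (1.02 ± 0.05) and Ptx3 (0.90 ± 0.05), liver in Prkag2 (0.93 ± 0.06) and Tmem54 (0.90 ± 0.08), heart in Grhl2 (0.68 ± 0.06), small intestine in Foxa2 (1.04 ± 0.07) and stomach in Plut (0.92 ± 0.15), which was lower in lung (-0.69 ± 0.15). The Plut call in lung was lost under normexp (-0.42) and quantile normalization (-0.49). Tor4a was lower in spleen (-0.64 ± 0.04, but -0.18 and not called under normexp) and thymus (-0.79 ± 0.04). Plut was also higher in small intestine (0.68 ± 0.15) and placenta (0.79 ± 0.15), calls lost under normexp (0.39 and 0.46), with scan date as a random block (0.68, adjusted p = 0.155, and 0.79, 0.0520), and without the female small intestine (0.34, 0.258) or the 13.5 dpc sample (0.48, 0.112). Hoxa3 was higher in placenta (0.54 ± 0.08), but not past the threshold under normexp (0.46) or without the 10.5 dpc sample (0.30). All are log2 differences from the mean of the other adult somatic tissues. Both sexes, or in placenta both stages of mixed sex, went in the same direction. The naming rule required this of the largest rises and falls, so for those it adds no evidence. The 2 small intestine arrays were the only ones on their scan date, and probes correlated within dates (0.576), so tissue and scan date cannot be told apart there. The 2 spleen and 2 placenta arrays shared a date with no other tissue. Differences of spleen from the other adult somatic tissues therefore cannot be told apart from that date, nor those of placenta from tissues other than spleen.

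Differences of testis rest on 1 array, with the spread of the other samples, and cannot be told apart from those of that array. It had less methylation at Pcdhga10 (-1.87 ± 0.19), Pcdha1 (-1.83 ± 0.21) and the imprinted genes Nap1l5 (-1.81 ± 0.12), Gnas (-1.56 ± 0.13), Slc38a4 (-1.55 ± 0.11) and Nnat (-0.62 ± 0.08). The imprinted list had 4 loci lower and 1 higher of 12 and did not pass as a set (median -0.30, adjusted p = 0.336). Rps4l (-1.46 ± 0.15) and Hspa1l (-0.88 ± 0.08), 1 of 2 spermatogenic markers, were also lower, as were Pax8 (-0.96 ± 0.09) and Hoxa3 (-0.72 ± 0.12). Ppp1r15b (1.08 ± 0.06) and Lhx3 (0.56 ± 0.11, but 0.38 and not called under normexp) were higher. In placenta 4 of 10 developmental transcription factors were higher (median 0.44, adjusted p = 2.3e-05; 0.548 with an estimated correlation): Otx2 (0.85 ± 0.09), Pax5 (0.78 ± 0.08), Wt1 (0.75 ± 0.08) and Foxa2 (0.57 ± 0.07), of which Wt1 (0.48) and Foxa2 (0.36) stood under the 0.5 threshold without the 13.5 dpc sample and under normexp (0.49 and 0.39). This was the only list to pass among 33 tests. Germline genes (5) passed as a set in no tissue. The 1 locus of that list lower in testis was Adamts5 (-0.72 ± 0.07), which only the wildcard brought into the list. Gnas was also lower in thymus (-0.30 ± 0.09) and lung (-0.30 ± 0.09) and higher in stomach (0.44 ± 0.09), all under the 0.5 threshold. In stomach Gnas passed it with scan date as a random block (0.54, adjusted p = 0.00229).

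**Figure D5:**
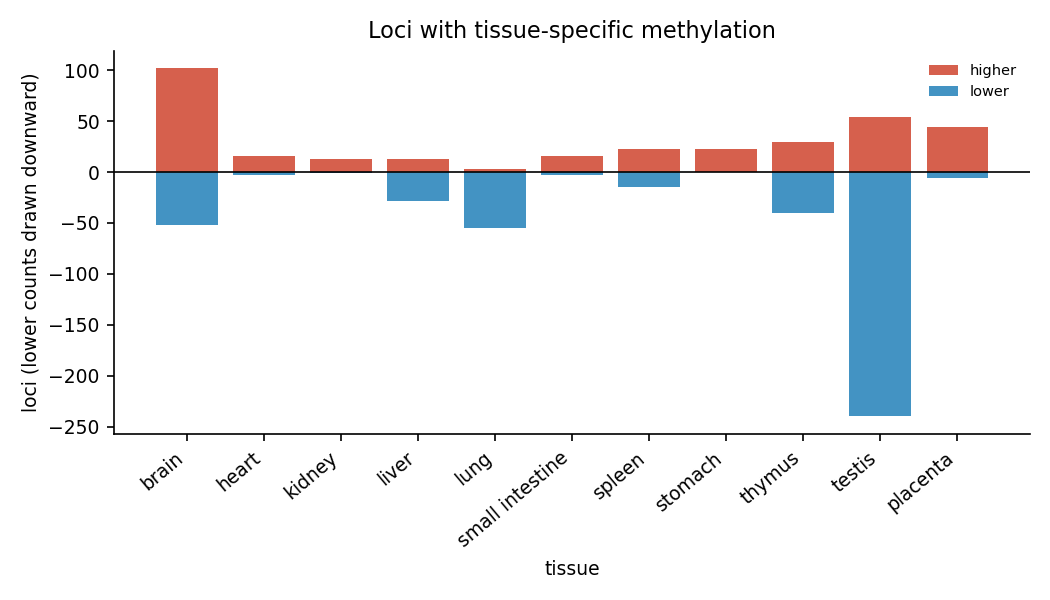
Loci with methylation at least 0.5 log2 higher or lower in 1 tissue than in the mean of the other adult somatic tissues. Testis is 1 array and placenta 2 stages.

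Among 3,664 loci 3,217 differed over the 9 tissues with both sexes, and among 98,200 probes 48,963. In that fit probes correlated within scan dates (0.660). Small intestine, spleen, stomach and kidney (male array 1) had both sexes scanned on 1 date, so tissue and date are partly mixed in these counts. Single-tissue contrasts called 336 loci higher and 443 lower (282 and 203 without testis in the fit). The 55 lower loci of lung depended on the scaling. They were 0 under normexp, 1 under quantile normalization, 23 with scan date as a random block and 84 when scaled by the median absolute deviation. Testis had 54 loci higher and 240 lower, brain 78 and 66 without the male array and 138 and 51 without the female array, placenta 44 and 6 (78 and 28 without the 10.5 dpc sample; 41 and 1 without the 13.5 dpc sample), and lung 3 and 55 (8 and 109 without the female array; 0 and 42 without the male). Probes labelled "di" differed more often than probes labelled "island" (59.7% against 34.8%), and in testis 12,131 of them were lower, against 2,275 island probes. The placental stages resembled each other (r = 0.972 over loci). Of 4 Hox loci 1 passed in each of brain, heart, kidney, placenta, spleen, testis and thymus, and the cell cycle, decidua, heart muscle, skeletal muscle and brain marker loci passed in no tissue.

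No correlation passed between methylation of a locus and expression of its transcripts over tissues. The median Spearman correlation of 4,523 transcripts from 3,077 loci was -0.036 (permutation p = 0.354; 95% of permuted medians from -0.064 to 0.064). Fam117a (-0.91), the Parkin co-regulated gene Pacrg (-0.88), Foxp1 (-0.87) and the autophagy gene Map1lc3a (-0.87) had the most negative values among named genes and Plut (0.90) the most positive, over 11 tissues each. None of these passed (permutation test with numpy, 0 of 4,523 adjusted and 349 unadjusted, of which 217 negative; smallest adjusted p = 0.204). With Pearson correlation 1 unnamed sense transcript passed (r = -0.962, adjusted p = 0.0452; -0.963 without liver and testis).

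The 2 arrays of 1 male kidney DNA gave r = 0.991 over loci (SD of the difference 0.0748) and 0.973 over probes. Male and female kidney gave 0.971 and 0.966 over loci, male and female arrays of 8 other tissues 0.958 to 0.973, and different tissues of 1 sex 0.846 to 0.983. Over probes the repeat was not the closest pair: male kidney array 1 and female kidney, scanned on 1 date, gave 0.980. Male kidney array 2 and female kidney gave 0.964 over probes, and male and female arrays of the 8 other tissues 0.928 to 0.976.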

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

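The exchange tests, the scan date and oligo-dT-only tests of sense and antisense transcripts, and both tests of loci without a chromosome were chosen only after the result was seen.

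Reverse-strand probes rose more with random priming than other probes. Forward probes matched on mean level rose by a median of 0.67, against 1.19, a difference of 0.53 (95% interval 0.41 to 0.66, 1,870 probes). Mean level alone therefore did not account for the larger rise under the main scaling. The match was not on detection with oligo-dT and was not repeated under other scalings. Under normexp with quantile normalization the excess over all probes was 0.16, against 0.72 under the main scaling, so a part of low signal in it stays open. If second-strand copies of forward transcripts were the cause, the rise should grow with the forward level, but the Spearman correlation over 427 genes was -0.31 (-0.40 to -0.23). No biological explanation was tested.

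Sense and antisense transcripts of a pair, such as Nusap1 and Oip5, rose and fell together over tissues. The median correlation was 0.16 after centring within scan dates and 0.14 on oligo-dT arrays alone, both above every re-pairing (highest 0.0548 and 0.0550), so neither scan date nor second-strand synthesis in random labelling is likely to explain it. Read on different arrays, the 2 transcripts still gave 0.0916 at the lower, against 0.0311 as the highest of the re-pairings, so a signal shared within 1 array may not account for all of it.

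Loci without a chromosome were more methylated in females at 27 of 2,517, against 0 of 1,128 autosomal loci. Of such loci 27 were called from the tissues scanned on different dates alone, and all of these were higher in each of the 4 tissues scanned on 1 date (median 0.94, lowest 0.51), so scan date is unlikely as the cause. X-linked loci whose chromosome is not given here might explain it, which stays open: the test of the larger share than among autosomal loci (Fisher's exact p = 4.4e-05) restates the pattern and could not have come out otherwise.

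Exchanging the labels within tissues gave no count as high as the real one, which was 1 of 100 in each case. Real and highest other counts were 11,111 and 9,325 for priming (1 tissue exchanged), 991 and 0 for sex in probes, and 55 and 22 for sex in loci (2 tissues exchanged).

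Some samples stood far from the others. In liver the female minus male difference of X-linked loci was low: the median was 0.66 (others 0.82 to 0.97), A230072E10Rik 0.59 (0.83 to 1.06), Syn1 0.38 (0.56 to 0.74), Dcaf12l2 0.0284 (0.36 to 0.70) and Ndufb11 0.51 (0.74 to 0.97). The female thymus array had 99.83% of input spots well above background (others 99.94 to 99.99). Of 34 groups tested chance marks about 1 in 20, and the values of liver are not independent of each other.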

How the results depend on the processing

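The tests with a 75th percentile over probes well above background on every array, 1 value per gene with reverse-strand probes, no small intestine and lung, centring within scan dates, and means over loci are alternatives chosen after seeing the data.

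Of 349 values of 14 comparisons 306 were counted as kept and 43 as moved. A factor of 1.5 was the limit for counts of calls alone. Medians of correlations were judged by direction and by whether they passed, whatever their size. The sense-antisense median on random arrays (0.066, against 0.145) therefore counted as kept. The repeated male kidney array counted as moved over probes and on the authors' table (0.973 each), although close to its value over loci (0.991). Of values of single genes 1,260 of 1,293 for priming, 2,717 of 2,831 for tissue expression, 340 of 357 for sex and 1,594 of 1,638 for tissue methylation kept their side of the threshold.

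Fewer probes tested lowered the priming count of 11,111: 3,720 of probes well above background on every array, 1,839 with 1 value per gene and 1,937 with reverse-strand probes included. Leaving out tissues gave 10,848 to 11,163. Snrpn turned to 0.0722 with the percentile over probes above background on every array, and Peg3 to -0.18 within scan date 3; the cause was not tested. With no tissue block Peg3 (0.87, adjusted p = 0.260) and Snrpn (adjusted p = 0.104) were not called.

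For tissue expression the same 3 alternatives gave 2,030, 1,556 and 1,336 probes in the F test, 2,678, 2,187 and 1,768 higher calls and 2,693, 1,801 and 1,336 lower calls, with fewer probes tested. Within scan dates 1, 2 and 3, with fewer arrays, the F test gave 2,042, 3,480 and 47 probes, with 2,250, 3,503 and 67 higher and 1,959, 3,169 and 15 lower calls. Lower calls fell to 2,636 with normexp with quantile normalization and 2,317 on the authors' table; the cause was not tested. Within scan date 3 calls were lost for Cyp2f2 (9.20), Clic3 (5.67), Mb (6.82) and Foxj1 (5.67) in lung, Prss32 (9.09), Cdx2 (4.74) and Ascl2 (0.53) in small intestine, and Gzmc (10.69), Dio3 (6.88), Cdkn1c (4.97), Slc38a4 (5.73), Ascl2 (4.53), Pramel13 (7.39), Rps4l (3.28), Peg3 (1.88) and Igf2r (1.62) in placenta. Without small intestine and lung the F test gave 6,198 probes.

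With a tissue left out sex differences in methylation ran from 866 probes (without spleen) to 1,509 (without thymus), and from 53 loci (without brain) to 122 (without thymus). With no tissue block 779 probes and 46 loci (1 lower) passed. Loci gave 55, also with at least 5 probes, since fewer units were tested. Normexp gave 110 loci (64 lower) and the tissues scanned on 1 date 91 (42 lower); the cause was not tested. Not called without the block were Gm5796 (-0.24, adjusted p = 0.149), H2-T23 (-0.16) and Cfap299 (-0.11). X-linked loci higher in females stayed at 18 or 19.

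For tissue methylation, loci in place of probes gave 3,217 in the F test (3,214 with at least 5 probes), with 336 (334) higher and 443 (442) lower calls. Normexp lowered the probe calls to 31,327 higher and 34,757 lower and the locus calls to 133 and 175. Quantile normalization gave 288 lower loci and leaving out the female lung array 501; the cause was not tested. Without testis 203 were left, as the 240 calls of testis itself drop out. The repeated male kidney array gave 0.973 over probes and 0.973 on the authors' table.

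The sense-antisense median ran from 0.066 to 0.181, always past every re-pairing, and the methylation-expression median from -0.067 to -0.018 with permutation p from 0.0676 to 0.762. Regions by coordinates were not run.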

Other observations

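The comparison of probe spreads between scan dates was among the tests chosen only after the result was seen.

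The fibroblast line SL10 rests on 1 oligo-dT array, with the spread of the other samples, so its differences cannot be told apart from those of that array. It had more Serpinb9b (8.61 ± 0.80 over the mean of the tissues), Timp1 (8.32 ± 0.77), Ptx3 (7.91 ± 0.74), Dlk1 (6.70 ± 1.03), Peg12 (5.82 ± 0.72), Hoxb9 (5.49 ± 1.47), Top2a (22.6-fold), the collagen gene Col1a1 (3.71 ± 0.58) and Serpine1 (2.99 ± 0.78). Lower were the endothelial Kdr (at least 169.6-fold) and Pecam1 (at least 58.3-fold), the macrophage gene Adgre1 (at least 18.7-fold), Rps4l (at least 500.7-fold), Ppp1r9a (at least 112-fold) and Sgce (at least 47.4-fold). Of 53 imprinted genes 5 rose and 8 fell (8 and 13 over the list alone), of 6 endothelial and macrophage markers 1 and 4 (1 and 5), and both fibroblast markers rose.

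Lower methylation in testis was set against expression in the same tissue, with the hypothesis that transcripts of such loci might be higher. The 325 transcripts had a median of -0.23 against -0.33 for others (limma camera, adjusted p = 0.285; 0.626 with an estimated correlation), which leaves it open. Of 18 such tests 1 passed, for the 75 transcripts of loci lower in brain (median 0.54 against -0.21, adjusted p = 0.0016), and not with an estimated correlation (0.191).

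Spleen and thymus of 1 sex gave r = 0.981 and 0.983 over loci, above male and female thymus (0.958). Male and female arrays scanned on 1 date differed over probes with an SD of 0.230 to 0.319, and those scanned on different dates with 0.333 to 0.468 (male kidney array 2 apart, 0.305).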
